A study of Mus musculus with 2 samples.

How the data were processed

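Single cells were sorted from the pancreas of adult mice in which a tamoxifen-inducible Cre recombinase is expressed from Tff2 and switches on a red fluorescent reporter at the Rosa26 locus. Per the labels' protocols, the tissue was digested with collagenase, dead cells were excluded with a DNA dye, and cells that were negative for CD45 and TER119 and positive for EpCAM and RFP were sorted and taken into 10x Genomics libraries. The labels give 2 samples, replicates of 1 group, and no control group. The time between tamoxifen and sorting is not given in the sources used here. Per the submitters' processing notes, Cell Ranger and the mm10 build were used, and their versions and roles are not given in the sources used here.

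The deposited table holds a raw count of unique molecular identifiers (UMIs) per gene and cell, per the labels and the whole-number values, for 14793 gene rows and 728 cells. The authors' filter on cells and genes is not given in the sources used here. Each cell in the table had at least 1004 UMIs, at most 29.7% of UMIs from mitochondrial transcripts and at least 38 genes with a UMI. Of the gene rows, 31 were 0 in every cell and 1553 had UMIs in 1 cell. The 4 symbols that stood on 2 rows were summed, which left 14789 symbols, of which 14333 (96.9%) matched a gene name in GENCODE M21 (GRCm38). Coordinates in the report are from that annotation. The labels do not tie cells to the 2 samples. Barcodes end in 1 (667 cells) or 2 (61 cells), and no label says which ending belongs to which replicate, so the table was treated as 1 sample. The endings were used only to divide the cells. The tests on sums per sample that had been planned were not run for that reason, and no p-value is given. Intervals are exact 95% intervals, Clopper-Pearson for shares of cells and Poisson for UMI counts and their ratios, and cover counting error only. Where a share or level is 0, the limit given in its place is 3 counts of the cells or UMIs, which is lower than the end of the exact interval. Cells within a mouse are not independent, and neither animal-to-animal variation nor free RNA is covered.

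Depth was 2353008 UMIs over all cells, with 2177260 under ending 1 and 175748 under ending 2. The median was 2085.5 UMIs and 730 genes per cell, and the range was 1004 to 53222 UMIs. The 20 acinar marker genes took 30.6% of all UMIs. A gene with 0 UMIs among the acinar-like cells was limited to 2.53 CPM (3 counts of the total), and among the ductal-like cells to 22.2 CPM. Barcodes were compared between endings, and 7 barcode sequences occurred under both, which is described in the report. Main values keep all 728 cells as deposited.

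Cells were clustered with scanpy 1.11.5 (Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9). Counts were scaled to 10000 UMIs per cell and log-transformed, 2000 variable genes and 20 principal components were used with 15 neighbours, and Leiden clustering was run at resolution 0.5 with seed 0. A cluster was named "X-like" from marker lists fixed before the data were examined, as the list with the highest mean log2 ratio of its markers over the other cells, with at least 3 markers seen in at least 10% of the cluster's cells. The lists covered acinar, ductal, endocrine, tuft, gastric or mucous, mesenchymal, mesothelial, endothelial, macrophage or dendritic, T or NK, B or plasma, neutrophil, erythroid and Schwann cells. Doublets were called with Scrublet in scanpy and kept in the main values. It called 3 cells (0.412%), at a score threshold of 0.221.

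UMIs were summed over the cells of a set and scaled to CPM, the counts of a gene relative to all UMIs of the set, with a prior of 0.5 counts on each sum for log2 ratios and a floor of 50 UMIs over both sets. A gene was called higher or lower at a fixed ratio of 2. Genes with 0 UMIs in a set have a bound computed with 3 counts over that set, and the genes called were also counted with these genes at their bound. A fold given as "at least" is this bound, which lies further from equal levels than the end of the exact interval. For cells compared on a share with a UMI or on genes per cell, each cell was thinned to 1000 UMIs, which left out 0 cells. Result lists fixed before the data were examined covered the sort gate, the trefoil family, acinar transcription factors, S and G2M phase, progenitor genes, acinar-to-ductal metaplasia, Reg and acute phase genes, the unfolded protein response, immediate early genes, secretagogue receptors, the Notch, Wnt and EGFR and RAS pathways, mitochondrial transcripts and ribosomal proteins. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression, as a description of this sample. In each comparison the 10 genes with the highest and the 10 with the lowest log2 ratio were named among genes over the floor with a UMI in at least 10% of the cells of the higher set, leaving out naming markers, mitochondrial and ribosomal protein genes and unnamed gene models. Tff2, Epcam, Ptprc and Mki67 were always named, with up to 4 members of a list by summed level over all cells. Because acinar markers take a large share of the UMIs of acinar-like cells, every ratio was also computed with these markers left out of the totals. In the text this is called the total without acinar markers. The result of 1 gene is not reported here.

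The scripts were tested on simulated counts with the UMI totals of the compared cells. Apart from the simulated changes, both sets were drawn from the same profile, that of the ductal-like cells or of the large acinar-like cluster. Differences in acinar marker share and variation between cells of a set were therefore absent. The rates below are not error rates for the genes called in the report. The comparison by Tff2 UMI was not simulated. For the acinar-like and ductal-like sets, with 14789 genes simulated, 100% of 50 genes simulated at a log2 ratio of 3 and 58% of 50 simulated at 1.5 were called higher, and 9.98% of 2715 genes with no simulated change passed the ratio of 2. For the 2 acinar-like clusters these were 100% of 50, 82% of 50 and 12.0% of 498, so a single gene just past a ratio of 2 is weak evidence there. Of genes simulated at log2 ratios of -3 and -1.5, 100% and 100% were called lower for the acinar-like and ductal-like sets. For the clusters these were 95.7% of 46 and 79.6% of 49, and the log2 ratios lay too high by a median of 0.427 and 0.214. Of 240 simulated cells of 3 classes, 100% were named as simulated. Alternatives covered the clustering resolution, the number of variable genes, filters on UMIs and mitochondrial share, doublets, thinning, the floor, the totals, the Tff2 threshold, the barcode endings, clustering without Tff2, equal weight for each cell, removal of 9 acinar-like cells that form an unnamed cluster when Tff2 is left out of clustering, and removal of the copy under ending 1 of each barcode found under both endings.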

Results

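The data were UMI counts from 728 cells sorted from mouse pancreas for EpCAM and for a reporter switched on by the Tff2 promoter. The labels name 2 replicates of 1 group, but cells could not be assigned to them, so all values come from 1 pooled sample of 2353008 UMIs and have no replicate check. The 667 cells whose barcode ended in 1 held 2177260 UMIs (median 2117 per cell), and the 61 cells whose barcode ended in 2 held 175748 (median 1857). The labels and the design text state only that Tff2-lineage cells were isolated and sequenced. The comparisons below ask which cell types the sorted population held and which of them carried Tff2 transcripts. They also ask how the acinar-like cells differed from ductal-like cells and among themselves, and how many cells carried cell cycle transcripts.

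Acinar-like cells, which make digestive enzymes, were the largest class, with 279 of 728 cells (38.3%, 95% interval 34.8 to 42.0). Ductal-like cells, which line the ducts that carry these enzymes, made up 36 cells (4.95%, 3.49 to 6.78). The other 413 cells (56.7%, 53.0 to 60.4) were in neither class, although the sort had selected EpCAM-positive and excluded CD45-positive and TER119-positive cells. They were endothelial-like (170 cells, 23.4%, 20.3 to 26.6), B or plasma-like (100 cells, 13.7%), T or NK-like (88 cells, 12.1%), macrophage or dendritic-like (20 cells, 2.75%), mesenchymal-like (18 cells, 2.47%) and erythroid-like (17 cells, 2.34%). Leading genes included Tcf15, Gpihbp1 and Car4 in the endothelial-like cluster and Iglc1, Igkc and Cd79a in the B or plasma-like cluster. They included Trbc1, Nkg7 and Cd3g in the T or NK-like cluster and Apoc1, Ambp and Spp1 in the ductal-like cluster. The macrophage or dendritic-like cluster was led by Retnla, C1qb and C1qc, the mesenchymal-like cluster by Smoc2, Igfbp6 and Dcn, and the erythroid-like cluster by the globin genes Hba-a2, Hba-a1 and Hbb-bs. No cluster was named endocrine, tuft, gastric, mesothelial, neutrophil or Schwann. Over all cells the endocrine markers had 59 UMIs, the tuft markers 73, the Schwann markers 21, the mesothelial markers 12 and the gastric or mucous marker 2. The neutrophil markers had 752 UMIs, of which 747 lay in the T or NK-like class. Of the fixed markers, 6 of 13 endocrine, 5 of 9 tuft, 3 of 4 mesothelial and 1 of 8 gastric or mucous genes were measured. These types were therefore searched for with few genes. A name required at least 3 markers, so no cluster could have been named gastric or mucous. A mesothelial name needed all 3 measured markers. The lack of these names does not show that such cells were absent.

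The composition differed between the barcode endings. Acinar-like cells made up 34.9% (31.3 to 38.7) of the 667 cells under ending 1 and 75.4% (62.7 to 85.5) of the 61 cells under ending 2, and cells that were neither acinar-like nor ductal-like 60.3% and 18.0%. The labels do not state whether an ending stands for a replicate. In addition, 7 barcode sequences occurred under both endings, all of them in acinar-like cells. The 7 cells under ending 1 held 1034 to 2138 UMIs, 14.1% to 20.5% of the UMIs of their namesakes under ending 2. Of their 10293 UMIs, 46 exceeded the count of the same gene in the namesake.

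**Figure D1:**
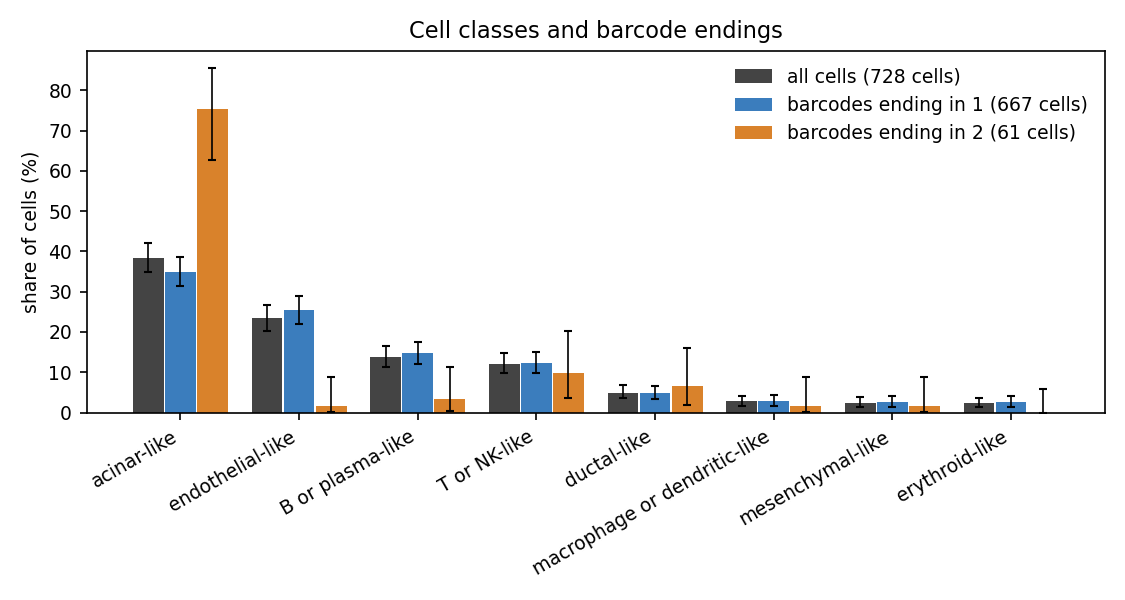
Share of cells (%) in each of the 8 named classes, for all 728 cells, the 667 cells whose barcode ended in 1 and the 61 whose barcode ended in 2, with bars from 0 and exact 95% binomial intervals. Acinar-like cells made up 38.3% of all cells, 34.9% under ending 1 and 75.4% under ending 2.

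Transcripts of the genes behind the sort were split between the classes. Epcam, which encodes the epithelial adhesion protein used in the sort (chromosome 17, 87635979 to 87651129, plus strand), was seen in 34 of 36 ductal-like cells at 866 CPM (717 to 1038). It was seen in 13 of 279 acinar-like cells (14.3 CPM, 8.36 to 23.0) and in 4 of the 413 other cells (3.87 CPM, 1.05 to 9.91). Ptprc, which encodes CD45, was seen in 73 of 208 cells of the immune classes (35.1%, 28.6 to 42.0; 226 CPM), in 2 of 279 acinar-like cells and in 0 of 36 ductal-like cells, which allows a share of cells with a UMI of up to 8.33%. Cdh1, Hbb-bs and the reporter were looked at after their values were seen. Cdh1, which encodes E-cadherin, had 46 UMIs in 37 acinar-like cells, 62 in 27 ductal-like cells and 1 in the other classes. Hbb-bs, a beta-globin gene, had 31531 UMIs in the 17 erythroid-like cells, 353016 CPM. The table has a row for RFP, with 2 UMIs in 2 acinar-like cells and 0 in the 413 cells outside the acinar-like and ductal-like classes, which allows up to 2.90 CPM, so the reporter transcript did not separate the classes at this depth.

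Tff2, which encodes a secreted trefoil peptide of mucous epithelia and drove the recombinase (chromosome 17, 31141049 to 31144282, minus strand), was concentrated in the acinar-like cells. They held 7788 of the 7892 Tff2 UMIs, 6573 CPM (6428 to 6721), and 272 of the 279 cells (97.5%) had at least 1 Tff2 UMI. The ductal-like cells held 12 Tff2 UMIs in 7 of 36 cells, 88.9 CPM. The acinar-like level was 74.0 times the ductal-like level (42.3 to 143) and 73.8 times the level over all other classes (60.9 to 90.5). Because Tff2 was among the genes used for clustering and among those that define the large acinar-like cluster, the ratios were also computed with clusters made without it, and were 69.5 and 63.3. Under ending 2 alone they were 29.0 (9.90 to 141) and 54.4 (23.2 to 168). With acinar markers left out of the totals, the ratios were 179 and 179. Of the trefoil family, Tff1 and Tff3 were not analysed here.

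Outside the acinar-like class, 86 of 449 cells (19.2%) had a Tff2 UMI. Thinned to 1000 UMIs per cell, the shares were 94.6% of acinar-like cells and 8.24% of the others, whose median depths before thinning were 2067 and 2092 UMIs. The non-acinar classes also held enzyme transcripts at 1.52% of their UMIs. Per 1000 acinar marker UMIs, they held 5.86 Tff2 UMIs (4.79 to 7.10), with 6.50 in endothelial-like cells (4.77 to 8.66), 6.01 in T or NK-like cells (3.62 to 9.41), 4.52 in B or plasma-like cells (2.47 to 7.59), 8.18 in macrophage or dendritic-like cells (3.28 to 16.9), 3.18 in mesenchymal-like cells (0.385 to 11.6), 4.34 in erythroid-like cells (0.893 to 12.7) and 5.75 in ductal-like cells (2.97 to 10.1). The intervals of these 7 classes overlapped. In acinar-like cells the value was 11.1 (10.8 to 11.3), so that of the non-acinar classes together was lower beyond counting error. The ductal-like share of cells with a Tff2 UMI (19.4%) stood near that of all non-acinar cells, so it is not read as Tff2 expression in ductal-like cells.

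**Figure D2:**
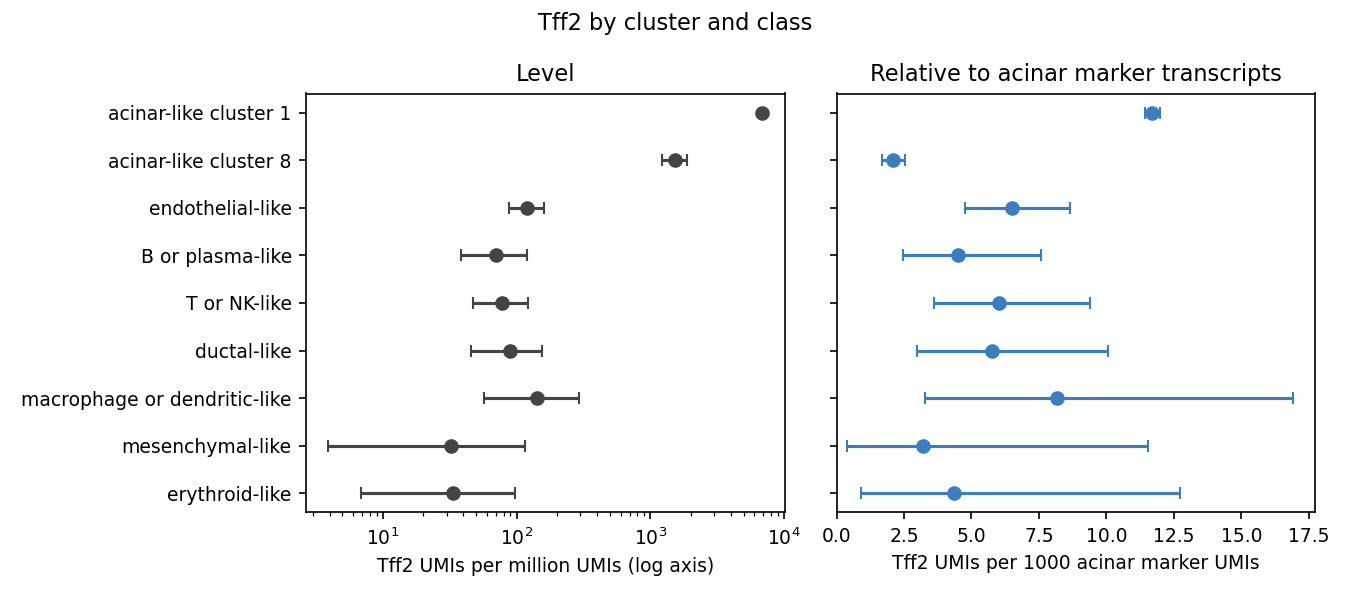
Left, Tff2 level in CPM on a log axis for the 2 acinar-like clusters and the 7 other classes; right, Tff2 UMIs per 1000 acinar marker UMIs on a linear axis, as points for UMIs summed over cells with exact 95% intervals. The acinar-like level of 6573 CPM was 74.0 times the ductal-like level. Relative to acinar markers, cluster 1 stood at 11.7, cluster 8 at 2.08 and the non-acinar classes together at 5.86.

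Against ductal-like cells, acinar-like cells were higher in the Reg and acute phase list and lower in the progenitor and acinar-to-ductal metaplasia lists. With no unlabelled acinar cells to compare, these lists contrast acinar-like with ductal-like cells and do not describe a trait of the Tff2 lineage. All 8 Reg and acute phase genes over the floor, secreted proteins of the regenerating family and pancreatitis-response factors, were at least 2-fold higher, among them Reg1 (log2 ratio 5.42, 5.09 to 5.79), Spink1, a trypsin inhibitor (6.08), Reg2 (5.42, 4.47 to 6.83) and Nupr1, a stress-induced chromatin protein (3.66, 3.21 to 4.18). Their median log2 ratio was 5.46, or 4.65 with genes at 0 set to their bound, at percentile 100 of matched random lists. The acinar naming markers had a median of 5.28 in the same comparison. Part of the ductal-like counts of this list may thus be free acinar RNA, which was not tested, so the sizes of these ratios are uncertain. The receptors for pancreatic secretagogues that passed the floor were both higher, Cckar, the cholecystokinin receptor, at least 6.27-fold and P2rx1, an ATP-gated channel, at least 5.62-fold. Of the acinar transcription factors over the floor, Ptf1a was at least 2.32-fold higher and Rbpjl, its partner in the acinar complex, had a log2 ratio of 2.05 (0.83 to 4.11). Xbp1, a regulator of secretory capacity, stood at 0.70 (-0.08 to 1.74), below the 2-fold rule, and passed it at 1.98 with the total without acinar markers.

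All 5 progenitor genes over the floor were at least 2-fold lower in acinar-like cells, with either total. They were Hes1, a Notch target (-5.59, -6.49 to -4.85), Sox4 (-4.66), Sox9, a ductal transcription factor and naming marker (-4.29), Prom1 (-3.57) and Cd24a (-2.78). The median was -4.29, or -3.02 with the total without acinar markers, at percentile 2.74. The 8 acinar-to-ductal metaplasia genes over the floor were all lower, but 5 of them, Spp1 (-8.68), Krt19 (-5.07), Clu (-4.35), Sox9 and Muc1 (-2.04), were ductal naming markers. The other 3 were Anxa2 (-5.94), Krt8 (-4.85) and Krt18 (-3.89), the keratins of simple epithelia. The list's median was -4.60, at percentile 0. With the other total it was -3.33, and Muc1, at -0.77, no longer passed the 2-fold rule. Hes1 was also the only Notch pathway gene over the floor, and Ctnnb1, which encodes beta-catenin, the only Wnt pathway gene (-3.09, -3.63 to -2.54). No EGFR and RAS pathway gene passed the floor, and their summed ratio was 0.0916 (0.0605 to 0.138).

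Unfolded protein response genes did not move one way. Of 18 over the floor, 6 were higher, 4 lower and 8 between, with Hspa5, the main chaperone of the endoplasmic reticulum, at 0.90 (0.30 to 1.64), Pdia6 at 0.26 (-0.40 to 1.08), Hsp90b1 at -1.07 and Calr at -1.86. Their summed level was equal within counting error (ratio 0.980, 0.867 to 1.11). With the total without acinar markers, 13 were higher and 0 lower, Hsp90b1 changed sign to 0.20, and the median moved from 0.43 to 1.70. The list stood at percentile 99.97 of matched lists. All 9 immediate early genes over the floor were lower (median -2.64, percentile 42.7), among them Junb (-4.17), Fos (-2.88), Jun (-2.38) and Jund (-1.88), and 7 of 9 with the other total (median -1.37). The median was -3.42 without 9 acinar-like cells rich in these transcripts. All 12 mitochondrial transcripts were lower (median -2.53, percentile 5.79), 7 of 12 with the other total. Of 87 ribosomal protein genes, 71 were lower and 16 between (median -1.65, percentile 82.2), against 2 higher, 14 lower and 71 between with the other total.

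In all, 113 genes were at least 2-fold higher and 778 lower among 1066 over the floor. With the total without acinar markers, the counts were 189 and 487, all log2 ratios rose by 1.27, and the median gene moved from -2.13 to -0.85. Acinar markers took 59.3% of the UMIs of acinar-like cells and 1.54% of those of ductal-like cells. The genes highest in acinar-like cells were Dmbt1, a secreted mucosal scavenger protein (7.26, 5.37 to 13.15), Erp27 (at least 18.4-fold), the serpin Serpini2 (at least 17.2-fold), Reg3d (at least 14.8-fold), Gatm, an enzyme of creatine synthesis (at least 12.0-fold), Reg3b (6.16, 4.26 to 12.05), Tff2 (6.15, 5.40 to 7.16), Spink1, Gp2, the main zymogen granule membrane protein (6.02, 4.83 to 8.07), and the aquaporin Aqp12 (at least 10.5-fold). The lowest were Apoc1 (at least 363-fold lower), the sodium pump subunit Atp1b1 (-9.80, -15.69 to -7.88), Ces1d (-9.16, -15.05 to -7.22), Tm4sf4 (-8.22), Apoe (-8.05), S100a11 (-8.00), Hhex, a transcription factor (-7.78, -11.16 to -6.17), Dcdc2a (-7.73, -11.12 to -6.12), Wfdc18 (-7.63, -11.02 to -6.02) and Eno1 (-7.59). Of these, Apoc1, Ces1d, Tm4sf4, Dcdc2a and Wfdc18 were also among the 10 genes that define the ductal-like cluster. The Reg3 genes are close copies of each other, and counts could be split between them.

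**Figure D3:**
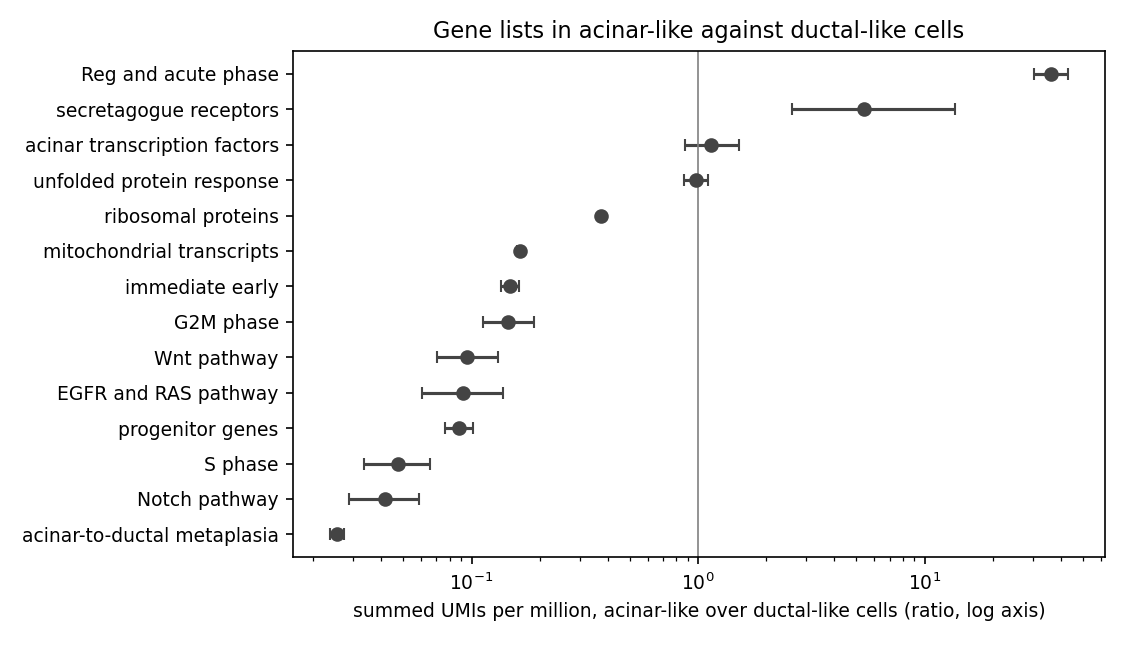
Ratio of summed CPM in 279 acinar-like over 36 ductal-like cells for 14 gene lists, on a log axis, with exact 95% intervals and a line at equal levels. The Reg and acute phase list stood at 36.0 and the acinar-to-ductal metaplasia list, which holds ductal naming markers, at 0.0256, and leaving acinar markers out of the totals would raise every ratio by 1.27 on the log2 scale, which takes the unfolded protein response (0.980) above equal levels.

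The acinar-like cells fell into a large cluster of 242 cells (cluster 1) and a small one of 37 (cluster 8), which differed in the mix of enzymes and in Tff2. Cluster 8 held Tff2 at 0.223 times the level of cluster 1 (0.180 to 0.273), and at 0.216 times in clusters made without Tff2. As a log2 ratio the first value was -2.16, and -1.52 with the total without acinar markers. It was higher in Reg2 (4.22-fold, 3.83 to 4.64), in the lipase Cel (4.02-fold), the elastase Cela2a (3.73-fold), the chymotrypsin-like protease Ctrl (3.37-fold) and the carboxypeptidase Cpa1 (2.09-fold). It was lower in colipase, Clps (0.235, 0.222 to 0.249), in Ctrc, a protease that degrades trypsinogen (0.249, 0.113 to 0.475), and in Nupr1 (0.322, 0.251 to 0.406). These enzymes are naming markers or were chosen after their values were seen, and Reg2, Cel, Cela2a and Ctrl are among the genes that define cluster 8, as Tff2, Clps, Ctrc and Spink1 are among those that define cluster 1. With the total without acinar markers, Nupr1 stood at -0.99 and no longer passed the 2-fold rule. Acinar markers made up 73.3% of the UMIs of cluster 8 and 58.5% of those of cluster 1, and the median cell held 130 genes against 409.5. At 1000 UMIs per cell the medians were 103 and 205.5 genes.

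Ribosomal protein transcripts in cluster 8 summed to 0.234 times the level in cluster 1 (0.220 to 0.248), with 75 of 87 genes lower (74 with genes at 0 set to their bound) and 0 higher, and 58 of 87 lower with the total without acinar markers. Mitochondrial transcripts summed to 1.99 times the level (1.88 to 2.10), with 5 of 12 higher and 10 of 12 with the other total. At resolution 1.0 these 37 cells held 23183 mitochondrial CPM, against 7401 in an acinar-like cluster of 96 cells. Another acinar-like cluster, of 118 cells, held 24934 CPM, or 19413 without 9 cells described below. A high mitochondrial level was therefore not particular to cluster 8. Of 8 immediate early genes over the floor, 7 were lower, or 5 with the other total and 5 with genes at 0 set to their bound, and Fos, with 0 UMIs in cluster 8, was at least 2.91-fold lower. Their median was -2.31, or -1.19 with genes at 0 set to their bound, at percentile 6.38. Much of this rested on 9 cells of cluster 1 that form an unnamed cluster in the clustering without Tff2, a step chosen after the values were seen. Without them the summed ratio moved from 0.202 (0.104 to 0.353) to 0.324 (0.167 to 0.570), 4 genes passed the floor, of which 3 were lower and 1 with genes at 0 set to their bound, Jun stood at -0.34 (-2.86 to 1.05), and Fos was at least 1.68-fold lower. Both secretagogue receptors, which also help define cluster 1, were lower with either total, Cckar at 0.224 times (2 UMIs in cluster 8, log2 interval -5.22 to -0.29) and P2rx1 at 0.250 (2 UMIs, -5.06 to -0.12). Of 17 unfolded protein response genes, 1 was higher, 6 lower and 10 between (median -0.69, or -0.42 and 4 lower with genes at 0 at their bound, percentile 93.4), against 2 higher and 2 lower with the other total. Of 8 Reg and acute phase genes, 2 were higher and 1 lower (median 0.09, percentile 91.5), and with the other total 3 were higher and 0 lower. Acinar transcription factors had 3 genes over the floor, of which Rbpjl was lower (2 UMIs in cluster 8, -1.83, -5.20 to -0.27, and -1.42, -4.80 to 0.15, without the 9 cells), and metaplasia genes 4, of which Krt18 was lower (3 UMIs, -1.59, -4.10 to -0.24). Krt18 did not pass the rule with the other total, at -0.95, and in both lists 1 gene was then higher. Cd24a, the only progenitor gene over the floor, was lower (1 UMI, -2.39, -8.29 to -0.47), and Ctnnb1, the only Wnt gene, stood between (-0.39, and 0.25 with the other total). No Notch, EGFR and RAS, S phase or G2M phase gene passed the floor.

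Over all genes, 26 were called higher in cluster 8 at a ratio of 2 and 427 lower among 675 over the floor, or 306 lower with genes at 0 set to their bound. With the total without acinar markers the counts were 66 and 310, all log2 ratios rose by 0.64, and the median gene moved from -1.47 to -0.83. Reg2, Pdia2, Slc39a5 and Reg3g, which help define cluster 8, were among the highest genes outside the naming markers. The others were Edem2 and Sdf2l1, which act in the quality control of the endoplasmic reticulum (1.76, 0.57 to 2.69, and 1.45, 0.10 to 2.46), Odc1, an enzyme of polyamine synthesis (1.59, 0.40 to 2.50), and Aup1, Itm2b and Pck2. Pdia2, a pancreatic disulfide isomerase, stood at 1.51 (1.27 to 1.74) and Slc39a5, a zinc transporter, at 1.18 (0.26 to 1.92). Reg3g (1.29), Aup1 (1.20), Itm2b (1.16) and Pck2 (1.12) had intervals that included 0. Among the lowest, Wbp5, Atp5j2, Pfdn5, Copz1, Vcp, Romo1, Atp5g2, Hist1h1c and Eif5b had 0 UMIs in cluster 8 and were between at least 2.95-fold (Eif5b) and at least 4.65-fold (Wbp5) lower, and Serf2 had 1 UMI (-4.16, -10.05 to -2.26). They include subunits of the ATP synthase, a translation factor and a prefoldin subunit. Amy1 and Amy2a5, and the trypsinogens Try4, Try5 and Prss2, are close copies, so values for single members are uncertain.

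**Figure D4:**
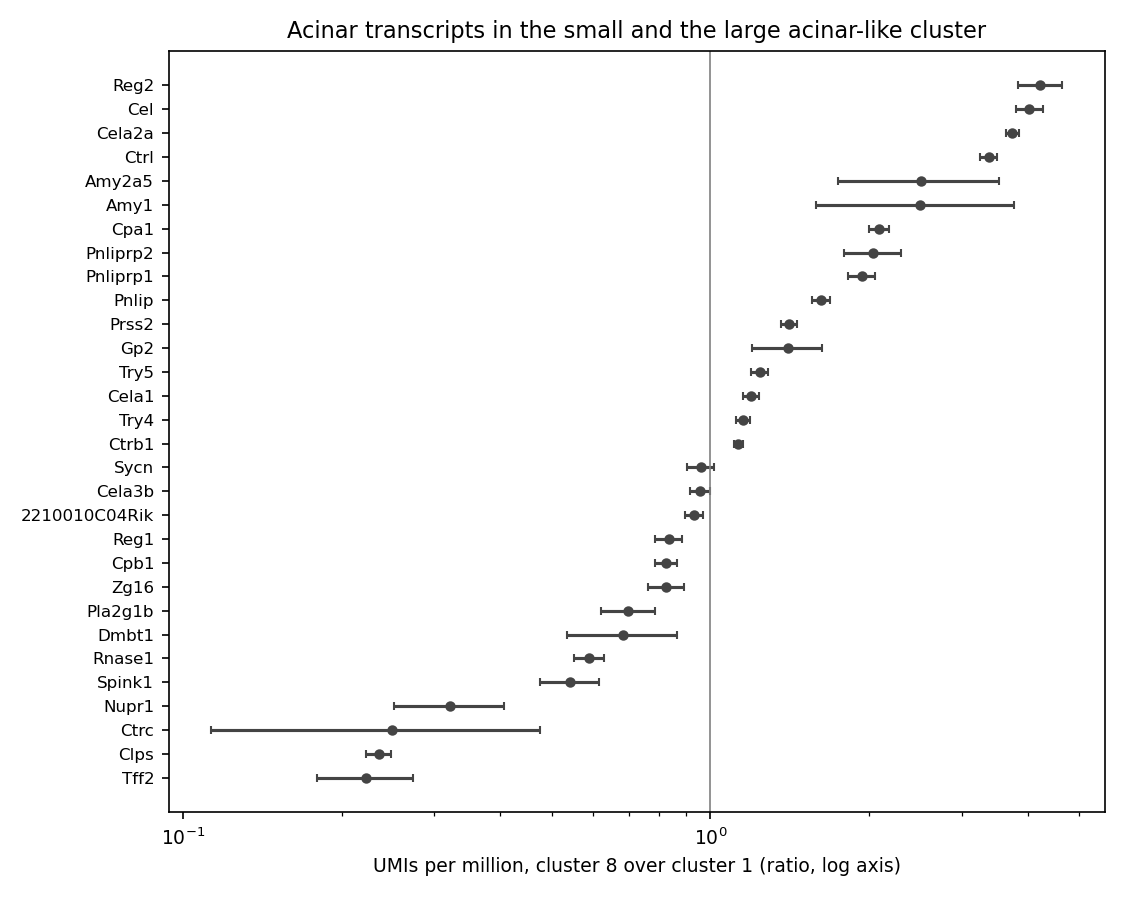
Ratio of CPM in cluster 8 (37 cells) over cluster 1 (242 cells) for acinar transcripts on a log axis, with exact 95% intervals and a line at equal levels. Reg2 stood at 4.22, Clps at 0.235 and Tff2 at 0.223; with acinar markers left out of the totals every ratio is higher by 0.64 on the log2 scale.

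Acinar-like cells without a Tff2 UMI were few. Thinned to 1000 UMIs per cell, 15 of 279 cells (5.38%, 3.04 to 8.71) had none, 8 of 242 in cluster 1 (3.31%, 1.44 to 6.41) and 7 of 37 in cluster 8 (18.9%, 7.96 to 35.2). Without thinning there were 7, so the rest of the 15 did hold a Tff2 UMI. Cluster 8 held Tff2 at 1525 CPM, a level at which a draw of 1000 UMIs can miss it by sampling alone. How many of the 15 lacked a Tff2 UMI through sampling was not tested. Here and below, "without Tff2" and "Tff2-less" mean no Tff2 UMI in the counts used, which were thinned unless stated. Between these 15 cells and the other 264, immediate early genes were 5.46 times higher in sum (4.40 to 6.74), with Btg2 (log2 ratio 3.28), Fos (3.22), Jun (2.91) and Ier2 (2.65) at least 2-fold higher, and the nuclear RNAs Malat1 (3.22, 3.07 to 3.37) and Xist (2.98, 2.49 to 3.45) were higher as well. Almost all of these UMIs came from 3 cells. When 9 cells that form an unnamed cluster in the clustering without Tff2 were left out, a step chosen after the values were seen, immediate early genes stood at 0.119 times (0.00299 to 0.670; 1 UMI in 12 cells), Malat1 at 0.439 (0.0895 to 1.31) and Xist at 0 UMIs. Mitochondrial transcripts were higher with these cells (2.82, 2.62 to 3.04) and without them (1.88, 1.69 to 2.09). However, cluster 8 held 7 of the 15 cells and stood at 1.99 times cluster 1 for mitochondrial transcripts, 0.234 for ribosomal proteins and 0.543 for Spink1. Both clusters held cells with and without a Tff2 UMI, but no comparison within a cluster was made. Differences in these genes between cells without and with Tff2, here and below, were therefore not separated from cluster membership.

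In this comparison 25 genes were called higher at a ratio of 2 and 62 lower among 230 over the floor, or 49 lower with genes at 0 set to their bound, and 15 were higher without the 9 cells. These counts depended on the setting, with 157 higher and 158 lower in unthinned counts, where 7 cells had no Tff2 UMI, and 74 and 133 at a floor of 20 UMIs. The other genes named as higher were Ubb (2.45, 1.39 to 3.33), H3f3b (2.23, 1.19 to 3.10), Sel1l, part of the degradation machinery of the endoplasmic reticulum (1.72, 0.74 to 2.51), and Rbpjl (1.43, 0.07 to 2.43), which had 0 UMIs in the 12 cells left without the 9. The lowest genes were P4hb (1 UMI, -3.23, -9.13 to -1.33) and 9 genes with 0 UMIs among the 15 cells. Of these, Fth1, a ferritin chain, was at least 1.80-fold lower, Hspa5 at least 1.55-fold and Ly6e at least 1.34-fold. Vcp, Eif2s2, Ndufs6, Cabp2, Wbp5 and Srp9 had bounds between 1.04 and 1.23, but their exact log2 intervals included 0. Ribosomal proteins had 24 of 77 genes lower (23 at the bound) and 2 higher (median -0.44, percentile 1.51), mitochondrial transcripts 8 of 10 higher, unfolded protein response genes 2 of 3 higher (Hspa5 was called lower, but not at its bound), and Reg and acute phase genes 1 of 6 lower, Spink1 (-1.16, -1.63 to -0.76). With the total without acinar markers, log2 ratios were lower by 0.06, and 6 of 10 mitochondrial and 1 of 3 unfolded protein response genes were higher. The acinar transcription factor list had Rbpjl alone over the floor and the metaplasia list Clu alone (-0.41, -2.19 to 0.72). No gene of the progenitor, secretagogue receptor, Notch, Wnt, EGFR and RAS or cell cycle lists passed the floor.

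Cell cycle transcripts were low in acinar-like cells. S and G2M phase genes summed to 165 CPM in acinar-like cells (143 to 190), or 406 with the total without acinar markers, against 1777 in ductal-like (1560 to 2017) and 2721 in endothelial-like cells (2559 to 2889). Erythroid-like cells, with 8 UMIs, stood at 89.6 CPM (38.7 to 176), not above the acinar-like level. The ratio of acinar-like to ductal-like cells was 0.0472 (0.0336 to 0.0655) for S phase and 0.146 (0.113 to 0.188) for G2M phase genes. With the total without acinar markers the gap was smaller, 110 against 963 CPM for S phase and 297 against 842 CPM for G2M phase genes. At 1000 UMIs per cell, at least 2 G2M phase UMIs were seen in 5 of 279 acinar-like cells (1.79%, 0.584 to 4.13), 7 of 36 ductal-like (19.4%, 8.19 to 36.0), 42 of 170 endothelial-like (24.7%, 18.4 to 31.9) and 25 of 100 B or plasma-like cells (interval 16.9% to 34.7%). Before thinning the shares were 9.68%, 66.7%, 55.3% and 36.0%. Acinar markers took 59.3% of the UMIs of acinar-like cells and 1.54% of those of ductal-like cells. Thinning to equal totals thus left fewer other UMIs in acinar-like cells, and the shares were not adjusted for this. Mki67, a protein of dividing cells, had 3 UMIs in 3 of 279 acinar-like cells, 1 UMI in 1 of 36 ductal-like cells and 16 UMIs in 5 of 170 endothelial-like cells. The higher list sums of other classes include genes such as Hmgb2, Tubb4b and Ctcf that resting cells also express, so they are not read as shares of dividing cells. Lgr5, a stem cell receptor, had 0 UMIs in the 279 acinar-like cells, which allows a share of cells with a UMI of up to 1.08%, and in the 36 ductal-like cells, which allows up to 8.33%.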

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

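Settings tied to barcode endings, to clusters made without Tff2, to equal weight for each cell, to the 9 cells of the unnamed cluster and to the repeated barcodes were chosen after the data were seen, and the set of main results was widened after the first values were seen. Over 28 results and 18 settings, 268 values were computed, of which 213 stayed within the counting interval of the main value (counts of genes within 1.5 times, list medians within the quartiles of the members), 55 moved beyond it and 0 changed direction. A change of direction could be recorded only for ratios and list medians, not for shares, levels or counts of genes. Of those that moved, 34 belonged to main results and 21 to others. Leaving out the 7 repeated barcodes moved none of the results (acinar-like share 37.7%, Tff2 ratio to ductal-like cells 73.7). Outside this set, leaving out the 9 cells turned immediate early genes and Malat1 in Tff2-less cells and left Xist and Rbpjl at 0 UMIs there. Totals without acinar markers changed the sign of 167 genes over the floor against ductal-like cells (Hsp90b1 among them), 84 between the clusters (Ctnnb1 among them) and 4 in Tff2-less cells.

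Under ending 2 alone, with 61 cells, the acinar-like share was 75.4%, cells in neither class 18.0%, cells with a Tff2 UMI 80.3% of all and 26.7% outside the acinar-like class, acinar-like Tff2 6260 CPM, its ratio 29.0 to ductal-like cells and 54.4 to all others, cell cycle transcripts 257 CPM and cells with G2M UMIs 0%. Asking for at least 2 Tff2 UMIs gave 37.2% of all, 92.5% of acinar-like and 2.90% of other cells, and thinning 41.3%, 94.6% and 8.24%. Totals without acinar markers, which raise acinar-like levels by construction, gave Tff2 16149 CPM, ratios 179 to ductal-like cells and 179 to others, 0.346 between the acinar-like clusters, 189 genes higher and 487 lower against ductal-like cells, and cell cycle transcripts at 406 CPM. Equal weight for each cell gave acinar-like Tff2 6021 CPM. A floor of 20 UMIs, which tests more genes, gave 182 higher and 2064 lower against ductal-like cells, and 74 and 133 for Tff2-less cells. Unthinned counts gave 2.51% Tff2-less cells with 157 genes higher and 158 lower. The filter at 1000 UMIs and 20% mitochondrial UMIs, which removed 11 cells, gave a Tff2 ratio of 0.301 between the clusters and 14 genes higher in Tff2-less cells, and leaving out the 9 cells gave 15. Asking for 3 G2M UMIs gave 0.358%. Apart from those set by construction, the causes were not tested.

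No paired analysis was possible because there is 1 group and cells do not map to the labelled replicates. For the same reason the planned runs without each replicate, the count models and the replicate block were not run. Depth limits the statements on small sets, as 3 UMIs equal 22.2 CPM in ductal-like cells, 48.7 in cluster 8 and 200 in Tff2-less cells.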

Other observations

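All tests in this part were chosen after the result they concern was seen. At resolution 1.0 the acinar-like cells split into 4 clusters. The small cluster of 37 cells kept its size, and the others held 118, 96 and 28 cells, of which 1, 25 and 17 had a barcode ending in 2. Unnamed gene models aside, the cluster of 96 was led by Reg3g, Clps, Gal, Reg3a, Nupr1 and Reg3b, which encode regenerating-family lectins, colipase, galanin and a stress-induced protein, with Reg3b at 899 CPM (833 to 970) against 538 (455 to 632) in the cluster of 118, and Nupr1 at 4068 (3924 to 4216) against 3057 (2854 to 3271). The cluster of 118 was led by Zfp395, Rbpjl and Larp1 and held 294 Rbpjl CPM (234 to 366) against 99.6 (78.2 to 125), or 153 (109 to 208) without the 9 cells described next. Since these genes define the clusters, the levels describe the split and do not test it. Depth and mitochondrial transcripts moved with this split, with median UMIs of 1646 in the cluster of 118 and 4540.5 in that of 96, and mitochondrial levels of 24934 CPM (19413 without the 9 cells) and 7401 CPM. The cluster of 28 was led by the trypsinogen copies Prss3 and Prss1, whose UMIs could be shared with their relatives. Since the endings, which no label explains, are spread unevenly over these 4 clusters, ending and state are confounded there. At this resolution, 11 cells led by S100a9 and S100a8, which encode the calprotectin subunits, separated from the T or NK-like class as neutrophil-like. Of the 170 endothelial-like cells, 131 formed a cluster led by Car4 and Aplnr and 28 a cluster whose leading genes included Fbln5, Sox17 and Gja4, genes known from capillary and from arterial endothelium. The other 11 joined the mesenchymal-like cluster, which grew from 18 to 29 cells.

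A group of 9 cells of the large acinar-like cluster, all with a barcode ending in 1, formed an unnamed cluster when Tff2 was left out of clustering. Malat1, a nuclear RNA, took 161945 CPM in them, 349 times the level in the other 270 acinar-like cells (318 to 384), and Neat1 was 82.0 times higher (54.1 to 124). Rbpjl, an acinar transcription factor, was 29.3 times higher (20.0 to 42.0), Btg2 245 times, Jun 83.9 times and Fos 65.1 times. Ctrb1, an abundant enzyme transcript, stood at 0.397 times the level (0.371 to 0.425) and Tff2 at 0.213 (0.128 to 0.333). Acinar markers made up 19.5% of their UMIs and mitochondrial transcripts 13.2%, 12.2 times the share in the other acinar-like cells (11.6 to 12.8). These genes were chosen after their values were seen, and no explanation was tested.

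Of the sorted cells, 56.7% were of vessel, blood and connective tissue classes that the gate for EpCAM should exclude. Droplets with only free RNA would share the same RNA mix, so cells were clustered and named on a random part of their UMIs and naming markers read on the rest, in 5 splits. This argues against free RNA for endothelial, B or plasma, erythroid and macrophage or dendritic-like cells (307 cells), where the median marker stood at least 12.8 times above the highest other class, and for T or NK and mesenchymal-like cells (106 cells), where the summed markers stood at least 68.1 (34.3 to 159) and 8.18 times (7.40 to 9.03) above it. Measures and parts were chosen after the values were seen: T or NK and mesenchymal-like cells had lowest medians of 10.9 and 39.7 but missed a demand that over 50% of markers pass 2 times at their lower limit in 2 of 10 cases, summed markers of macrophage or dendritic-like cells stood at only 1.69 to 1.85 against B or plasma-like cells, which share MHC class II genes, and forms on all UMIs, in which naming conditions the outcome, were dropped. Of these cells, 0.242% (up to 1.34%) had over 10% of UMIs from acinar markers, so few of their droplets also held an acinar cell. Whether joined acinar cells carried them through the sort is undecided. A droplet rich in acinar markers could be named acinar-like and leave this set, and joined cells could come apart after the sort. Cells that passed the sort despite lying outside the gate remain open, since the Ptprc level in the immune classes, 134 times that of acinar-like cells (36.2 to 1119), follows from how these classes were named and decides nothing. Labelling of these cells by recombination stays undecided because reporter UMIs numbered 0 there and 2 in acinar-like cells, and no biological explanation was tested.

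The 7 barcodes under both endings may each be 1 cell counted under both. Chance sharing is argued against because the namesake ranked first by likelihood among the 46 acinar-like cells under ending 2 for 7 of 7 barcodes. Of the UMIs of the smaller copies, 0.437% (0.319 to 0.585) lay in genes unseen in the larger copy, against 3.94% on average when copies were paired with another of the 7 cells, which fits the same molecules appearing in both. The 7 were among the 8 deepest cells under ending 2 (the other was B or plasma-like, with 8193 UMIs and no copy), whereas 0 of 61 equally deep cells under ending 1 had a copy under ending 2. Reads assigned to the wrong library are 1 candidate explanation that these counts alone do not separate from others, and no biological explanation was tested.

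The small acinar-like cluster, with few genes and little Tff2, held 2.08 Tff2 UMIs per 1000 acinar marker UMIs (1.68 to 2.55). Non-acinar cells other than erythroid-like ones held 5.92 (4.82 to 7.20), so the Tff2 share of the cluster did not match the RNA mix in those cells. This does not decide on free RNA in empty droplets, since low Tff2 is part of the pattern in question and empty droplets were not measured. Shallow sampling is argued against by the median of 205.5 genes in the large cluster at 1000 UMIs per cell, against 103 (75th percentile 113) in the small one. Loss of short transcripts, which could come from degraded RNA, cannot be told apart from a cell state. The ratio of the small to the large cluster rose with transcript length across 28 acinar genes (Spearman rho 0.526, Pearson r 0.364, genes are not independent replicates) but hardly across all 624 genes with a length (rho 0.120) or the 544 without ribosomal proteins (rho 0.0556), a second condition that was added after the first value was seen. No biological explanation was tested, and a distinct secretory state stays a hypothesis.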
